A study of Mus musculus with 6 samples.

How the data were processed

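Poly(A)-selected RNA from 6 libraries of immortalised mouse bone marrow-derived macrophages was sequenced, 3 from wild-type (WT) cells and 3 from cells labelled as knockout (KO) for 4-1BBL, the TNF family ligand encoded by Tnfsf9. Per the labels, all cells had received IL-4 at 10 ng/ml for 24 hours, and the cells had been immortalised with retroviruses carrying v-raf and v-myc. The labels give 1 replicate number per library and do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Libraries from cells without IL-4 were not analysed here, so the values are levels after IL-4 and not responses to it.

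The deposited values are FPKM per Ensembl gene, in 1 column per library, for 54532 genes. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 build were used. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The labels' protocol names both a directional and a non-directional way of making the libraries, so reads of a gene and of an overlapping antisense gene cannot be assumed to have been separated. Gene symbols and positions were taken from GENCODE M21, which is on the same build, and 54495 of the gene identifiers matched, leaving 37 without a symbol.

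The depth of each library was recovered from the deposited FPKM. Multiplying FPKM by the exon length of the gene gave values that stepped in multiples of what 1 fragment is worth, and in each library about 98.0% of the values up to 200 fragments were whole within 0.1 of a fragment, against 20% by chance. The recovered depth was 21.4, 20.7 and 22.3 M (mega) assigned fragments for WT replicates 1 to 3 and 26.4, 19.7 and 19.1 M for KO replicates 1 to 3. Fragment numbers were recovered for 54213 genes and were used for the detection floors and for 1 added alternative, not for the tests reported first. A gene at 0 in a whole group was set against a floor of 3 fragments per library, and a fold against such a group is written as a lower bound. Floors cover counting error only, since fragments were counted without molecular identifiers.

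No pair of libraries shared a value above 0 at the same gene to the printed precision, and all 6 were used as separate samples. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 10843. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), KO minus WT, with Benjamini-Hochberg adjustment. Fold changes in log2 are on that scale, which understates the change of weakly expressed genes. Folds given for single genes are ratios of mean FPKM. The 2-fold and 16-fold limits used to count tested genes in the main fit were applied on the log2(FPKM + 1) scale. For Tnfsf9 an exact two-sided permutation test of mean FPKM was also run, whose smallest possible p with 3 against 3 libraries is 0.1.

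Gene lists were fixed before the data were examined, 31 in all, of which 6 address the activation state and metabolism named by the study. Each list with at least 3 tested members was compared with all other tested genes by camera, in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists. The same test with an estimated correlation was an alternative. Counts of list members that rose or fell use the adjustment over all tested genes, and the count adjusted over the list alone is given beside it where it differs.

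The genes named were also chosen by a rule fixed before the data were examined. They are Tnfsf9 and its receptor gene Tnfrsf9, the 6 largest increases and the 6 largest decreases among genes past an adjusted p of 0.05 with a mean of at least 10 FPKM and no overlap between the groups, without predicted genes and pseudogenes by symbol, and a short set of activation and metabolism genes whatever their values. The rule adds the 3 members with the largest change in each of the 6 central lists and the 2 with the largest change in each other list. Some genes the rule takes are not reported here. Other genes given with values are marked as chosen after their values were seen, apart from 3 strain markers that were chosen before.

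Genes with a near-identical copy elsewhere in the genome were identified with BLAST+ 2.17.0+ from the annotated transcripts, as an alignment of at least 95% identity over at least 80% of the shorter transcript and at least 150 bases. How fragments of such genes were divided depends on the counting, so their values are treated as uncertain, as are those of genes whose exons overlap another expressed gene. On simulated reads drawn from the WT means at the real depths, with 10258 genes tested, the limma step recovered 74.2% of genes changed by 1.5-fold, 89.6% of those changed by 2-fold and 95.2% of those changed by 4-fold, and 6.44% of its calls were false. Of the 10258 simulated genes 10032 were unchanged, whereas 60.8% of the real tested genes passed, so these rates do not carry over to the real data. None of 100 simulated unchanged lists passed camera at 0.05. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes vary together. In the real lists the estimated inter-gene correlation was highest for mitochondrially encoded genes (0.620) and glycolysis (0.160). It was 0.0246 for oxidative phosphorylation, 0.0291 for the TCA cycle, -0.0229 for alternative activation and -0.0136 for interferon-stimulated genes. Several lists with an estimate below the preset also had larger p-values in camera with an estimated correlation. A call lost in that alternative does not by itself point to correlated genes.

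Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, rescaling to TPM, median ratio scaling, quantile normalization, limma without trend, the replicate number as a block, an estimated inter-gene correlation and leaving out each library in turn. A fit without genes that have a near-identical copy and limma's voom on the recovered fragment numbers were added after the data had been seen. Plots were drawn with matplotlib 3.10.9.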

Results

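RNA was sequenced from immortalised mouse bone marrow-derived macrophages, a growing line made from cultured marrow macrophages by retroviral v-raf and v-myc, after 24 hours with IL-4 at 10 ng/ml. IL-4 is the cytokine that drives alternative, anti-inflammatory activation of macrophages. The 6 libraries comprised 3 from WT cells and 3 from cells labelled as lacking 4-1BBL, a TNF family ligand. The depth recovered from the deposited FPKM was 20.7 to 22.3 M (mega) assigned fragments per WT library and 19.1 to 26.4 M per KO-labelled library. The study's title poses the question addressed by the only comparison of the design, namely how the presence of 4-1BBL bears on anti-inflammatory gene expression and on metabolism in these cells.

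Tnfsf9, the gene of 4-1BBL, was expressed in all 6 libraries. It lies on chromosome 17 at 57105325 to 57107757 in mm10 (ENSMUSG00000035678). Its level was 14.6, 10.4 and 12.05 FPKM in WT replicates 1 to 3 and 10.7, 10.7 and 11.4 FPKM in KO-labelled replicates 1 to 3. The group means of 12.3 ± 2.10 and 10.9 ± 0.414 FPKM (SD, n = 3 each) did not differ beyond the spread between libraries, with an exact two-sided permutation p of 0.4, where 0.1 is the smallest p this design allows. In limma the log2 fold change was -0.15 ± 0.11 (SE), with a 95% interval from -0.41 to 0.11 and a Benjamini-Hochberg adjusted p of 0.273. The labels do not say which part of the gene the knockout removes, so transcript outside a removed part could still be counted, and 14.9% of the exon length of Tnfsf9 overlaps the antisense gene Gm11110. The transcript level therefore neither bears out nor contradicts the label, and the group is called KO-labelled throughout. Tnfrsf9, the receptor of 4-1BBL, had 1.71 ± 0.111 FPKM in WT and 0.236 ± 0.0974 FPKM in KO-labelled libraries (SD, n = 3), from 300 and 44 fragments, and was below the level for testing.

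The WT and KO-labelled cells differed in most expressed genes. Arg1, the arginase that marks alternative activation, rose from 0.659 ± 0.162 FPKM in WT to 462 ± 26.7 FPKM in KO-labelled libraries, a 701-fold difference. C1qb, a complement subunit made by tissue macrophages, was at 0 in all WT libraries and at 116 ± 8.92 FPKM in KO-labelled ones, at least 901-fold higher. In the other direction Mycn, a Myc family transcription factor, fell from 280 ± 4.53 FPKM in WT to 0.0301 ± 0.0289 FPKM, and Cldn11, a tight junction gene, fell from 110 ± 2.46 FPKM to 0 in all KO-labelled libraries, at least 1462-fold lower.

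Of 10843 genes tested, 6594 (60.8%) passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 3321 higher and 3273 lower in KO-labelled cells. With a change of at least 2-fold on the log2(FPKM + 1) scale, 1465 genes passed, 784 higher and 681 lower. On that scale changes of 16-fold or more were found for 69 and 48 genes. These counts leave out some genes whose ratio of mean FPKM was beyond the limit, such as Acp5, 18.2-fold lower. The libraries of the 2 groups did not overlap for 67.4% of tested genes, against 10% by chance. Across all tested genes the median log2 fold change was 0.01. The correlation of log2 values across genes, which are not independent replicates, was at least 0.989 within WT, at least 0.981 within KO-labelled libraries and 0.840 to 0.851 between the groups.

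**Figure D1:**
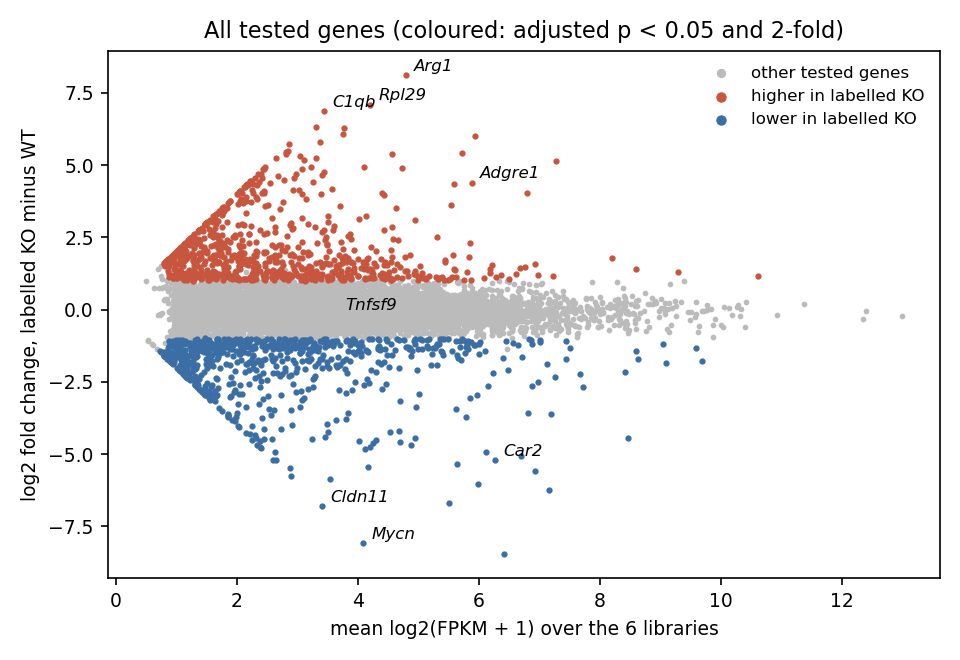
Mean log2(FPKM + 1) over the 6 libraries (x axis) against the log2 fold change, KO-labelled minus WT (y axis), for each tested gene. Coloured points passed an adjusted p of 0.05 and 2-fold (784 higher, 681 lower), and Tnfsf9 lies among the unchanged genes at -0.15.

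The remaining genes with the largest changes included Basp1, a membrane-associated protein gene, which rose from 0.111 ± 0.174 to 87.3 ± 5.92 FPKM, and AI506816, which rose from 0.658 ± 0.0540 to 110 ± 4.44 FPKM. Car2, a carbonic anhydrase, fell from 466 ± 3.38 to 11.6 ± 1.05 FPKM (40.02-fold). Chst1, a sulfotransferase, fell from 53.8 ± 2.46 to 0.0190 ± 0.0328 FPKM and the X-linked homeobox gene Rhox5 fell from 48.2 ± 3.65 to 0.0965 ± 0.0838 FPKM. For these 5 genes the limma adjusted p (Benjamini-Hochberg) was at most 4.00e-08. The rule for large changes also named Rpl29, higher with a log2 fold change of 7.10, and Rps3a2, lower with -6.04, but both have near-identical copies among ribosomal protein genes and pseudogenes and their values are uncertain. Among the 1465 genes past 2-fold, 201 (13.7%) have such a copy, as do 1298 of all 10843 tested genes, which is a similar share.

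The groups also parted on the Y chromosome. Ddx3y was at 10.8 ± 1.13 FPKM and Eif2s3y at 10.4 ± 0.627 FPKM in KO-labelled libraries (n = 3), with 1 fragment of Ddx3y and 0 of Eif2s3y over the 3 WT libraries, and Uty (2.40 FPKM) and Kdm5d (1.85 FPKM) were likewise at 0 in WT. Xist, the transcript of the inactive X chromosome, had 0 fragments in all 6 libraries. Uty, Kdm5d and Xist belong to the sex-linked list and were chosen for naming after their values were seen. The 3 tested members of the sex-linked list were higher (camera adjusted p = 0.0052, and adjusted p = 0.146 with an estimated correlation). The libraries compared for each gene group also differ in these Y-linked transcripts.

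Genes of alternative activation were higher in KO-labelled cells. Of 31 tested members of the list, 25 rose, 3 fell and 3 did not pass, with a median log2 fold change of 2.46, or 2.82 with genes at 0 in WT set to their lower bound. Without the filter on expression the median was 1.00 over 46 members, 29 of them higher and 4 lower, and over the 31 it was 4.41 with a pseudocount of 0.1, 3.32 after rescaling to TPM and 4.26 with voom over 30, so its size depends on the scale. The mannose receptor gene Mrc1 was at 0 in WT and at 29.7 ± 1.05 FPKM in KO-labelled cells (at least 1352-fold higher), and the arginine transporter gene Slc7a2 was at 0 and at 28.4 ± 1.10 FPKM (at least 1857-fold higher). The chitinase-like gene Chil3 and the lipid-sensing nuclear receptor gene Pparg were also at 0 in WT, and reached 15.1 ± 1.18 and 12.6 ± 0.681 FPKM (at least 176-fold and at least 266-fold higher). With Arg1, these 5 genes had adjusted p of at most 5.38e-08 in limma (Benjamini-Hochberg). Camera placed the list above other genes with an adjusted p of 6.87e-10, and of 0.0402 with an estimated correlation.

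Parts of the IL-4 receptor pathway differed as well. Il4ra, the receptor's specific chain, was 11.7-fold higher in KO-labelled cells, with 0.398 ± 0.0779 FPKM in WT and 4.65 ± 0.329 FPKM in KO-labelled libraries (limma adjusted p = 2.76e-06, Benjamini-Hochberg). Socs1, a feedback inhibitor of cytokine signalling, rose from 0.870 ± 0.387 to 10.5 ± 2.02 FPKM. Stat6, the pathway's transcription factor, was at 38.2 ± 1.09 and 35.2 ± 0.463 FPKM and did not pass (limma adjusted p = 0.0506), although it passed under 4 of the alternatives, with an adjusted p of 0.0365 without a filter. Of 22 tested pathway components, 10 rose, 5 fell and 7 did not pass, or 10 and 6 adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.208). Irf4 was at 0.377 ± 0.123 and 0.471 ± 0.172 FPKM and Retnla at 0 and 0.321 ± 0.120 FPKM, the latter from 12 fragments, and neither reached the level for testing.

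**Figure D2:**
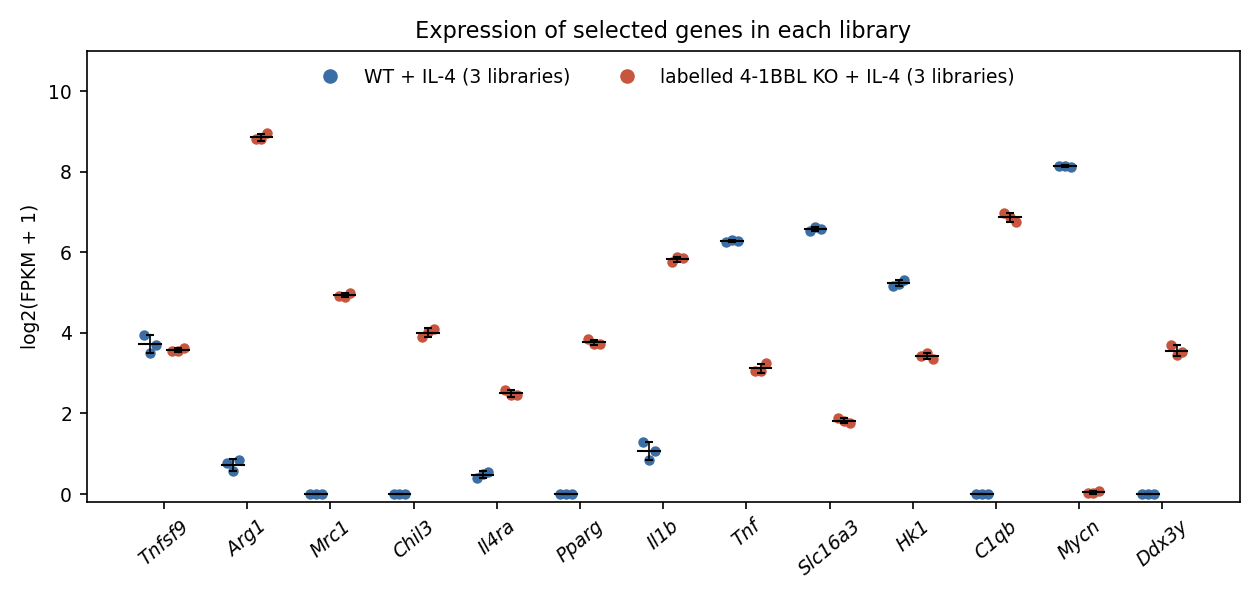
Expression of 13 named genes as log2(FPKM + 1) (y axis) in each of the 3 WT (blue) and 3 KO-labelled (red) libraries, where points are libraries, horizontal bars group means and error bars SD. Tnfsf9 overlaps between the groups, while Mrc1, Chil3, Pparg and C1qb lie at 0 in WT and Mycn lies near 0 in KO-labelled libraries.

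Classical inflammatory genes moved in both directions. Of 37 tested members, 20 rose, 14 fell and 3 did not pass, or 20 and 15 adjusted over the list alone. The cytokine gene Il1b rose from 1.11 ± 0.332 to 55.7 ± 2.62 FPKM (50.1-fold), the acute phase gene Saa3 rose from 0.608 ± 0.269 to 36.5 ± 3.85 FPKM (60.0-fold), and the scavenger receptor gene Marco was at 0 in WT and at 20.8 ± 1.86 FPKM in KO-labelled cells (at least 286-fold higher). Tnf fell from 76.5 ± 1.04 to 7.70 ± 0.702 FPKM (9.93-fold) and Nos2, the inducible nitric oxide synthase, fell from 47.8 ± 1.12 to 17.1 ± 0.363 FPKM (2.79-fold). These 5 genes had adjusted p of at most 3.54e-07 in limma (Benjamini-Hochberg). Il6 was at 0.0456 ± 0.0404 and 0.380 ± 0.199 FPKM and was not tested. The list as a whole did not stand apart from other genes (median log2 fold change 0.16, camera adjusted p = 0.288).

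Glycolysis genes were lower in KO-labelled cells in most cases. Of 25 tested members, 6 rose, 16 fell and 3 did not pass. The lactate exporter gene Slc16a3 fell 37.3-fold, from 94.4 ± 3.23 to 2.53 ± 0.154 FPKM, the enolase gene Eno2 fell 13.8-fold, from 8.21 ± 0.427 to 0.593 ± 0.104 FPKM, and the hexokinase gene Hk1 fell 3.78-fold, from 36.8 ± 1.90 to 9.73 ± 0.537 FPKM (limma adjusted p of at most 6.11e-07, Benjamini-Hochberg). The glucose transporter gene Slc2a1 fell from 80.4 ± 4.76 to 57.7 ± 4.85 FPKM, whereas Hk2 rose from 27.0 ± 0.792 to 31.0 ± 1.31 FPKM. The lactate dehydrogenase gene Ldha, which has a near-identical copy, was at 1061 ± 12.3 and 853 ± 27.2 FPKM with a log2 fold change of -0.32 (limma adjusted p = 0.000406), and under quantile normalization this was 0.0038 with an adjusted p of 0.932. Hif1a, the transcription factor that drives many glycolysis genes, fell from 45.6 ± 0.388 to 19.2 ± 0.772 FPKM. The list's median log2 fold change was -0.47 and its camera adjusted p 0.00688, but the adjusted p was 0.283 with an estimated correlation and 0.0743 without the members that have a near-identical copy, a comparison added after the data had been seen, in which the median of the 18 left was -0.38 with 6 higher and 11 lower.

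Genes of mitochondrial respiration were modestly lower. Of 77 tested nuclear-encoded genes of oxidative phosphorylation, 6 rose, 42 fell and 29 did not pass, or 7 and 42 adjusted over the list alone, with a median log2 fold change of -0.22, or -0.13 after rescaling to TPM, where 8 rose and 35 fell. Rescaling to TPM also raised the median of all tested genes by a similar amount, so the shift of the list against other genes was about the same. Uqcrh of complex III fell from 162 ± 4.33 to 79.3 ± 9.88 FPKM, and of complex I Ndufs8 fell from 209 ± 4.54 to 112 ± 5.19 FPKM and Ndufb5 from 14.6 ± 0.878 to 6.86 ± 0.520 FPKM, where 12.3% of the exon length of Ndufb5 overlaps an antisense gene. These 3 had adjusted p of at most 6.55e-05 in limma (Benjamini-Hochberg). Camera gave the list an adjusted p of 0.00022, and of 0.125 with an estimated correlation.

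In the tricarboxylic acid cycle 18 of 26 tested genes fell, 3 rose and 5 did not pass, with a median log2 fold change of -0.35. The malate dehydrogenase gene Mdh1 fell from 120.0 ± 2.14 to 71.0 ± 7.47 FPKM and Dlst, of the oxoglutarate dehydrogenase complex, fell from 29.3 ± 0.886 to 17.5 ± 0.752 FPKM. Both had limma adjusted p of at most 0.000141 (Benjamini-Hochberg). The camera adjusted p was 0.00584, and 0.173 with an estimated correlation. Of 12 tested genes encoded in the mitochondrial genome 8 fell, none rose and 4 did not pass, among them mt-Cytb, which fell from 734 ± 27.2 to 431 ± 33.2 FPKM (camera adjusted p = 0.0196, adjusted p = 0.431 with an estimated correlation), and 8 of the 12 have a near-identical copy. The adjusted p of this list was 0.287 without the members that have such a copy and 0.0682 under quantile normalization, with medians of -0.25 over the 4 left and -0.29 over the 12 against -0.38.

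Fatty acid oxidation and uptake genes did not move as a group. Of 32 tested members, 13 rose, 7 fell and 12 did not pass (median log2 fold change 0.09, camera adjusted p = 0.144). The fatty acid uptake and carrier genes Cd36 and Fabp4 rose from 7.24 ± 0.113 to 55.2 ± 4.00 FPKM and from 3.16 ± 0.179 to 26.2 ± 5.69 FPKM. Decr1, an enzyme of unsaturated fatty acid breakdown, was at 0 in WT and at 4.18 ± 0.621 FPKM (at least 116-fold higher). Cpt1a, which controls entry of fatty acids into mitochondria, rose from 7.82 ± 0.579 to 9.76 ± 0.447 FPKM, and the coactivator gene Ppargc1b fell from 5.19 ± 0.377 to 2.57 ± 0.383 FPKM. These 5 changes had limma adjusted p of at most 0.00878 (Benjamini-Hochberg).

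**Figure D3:**
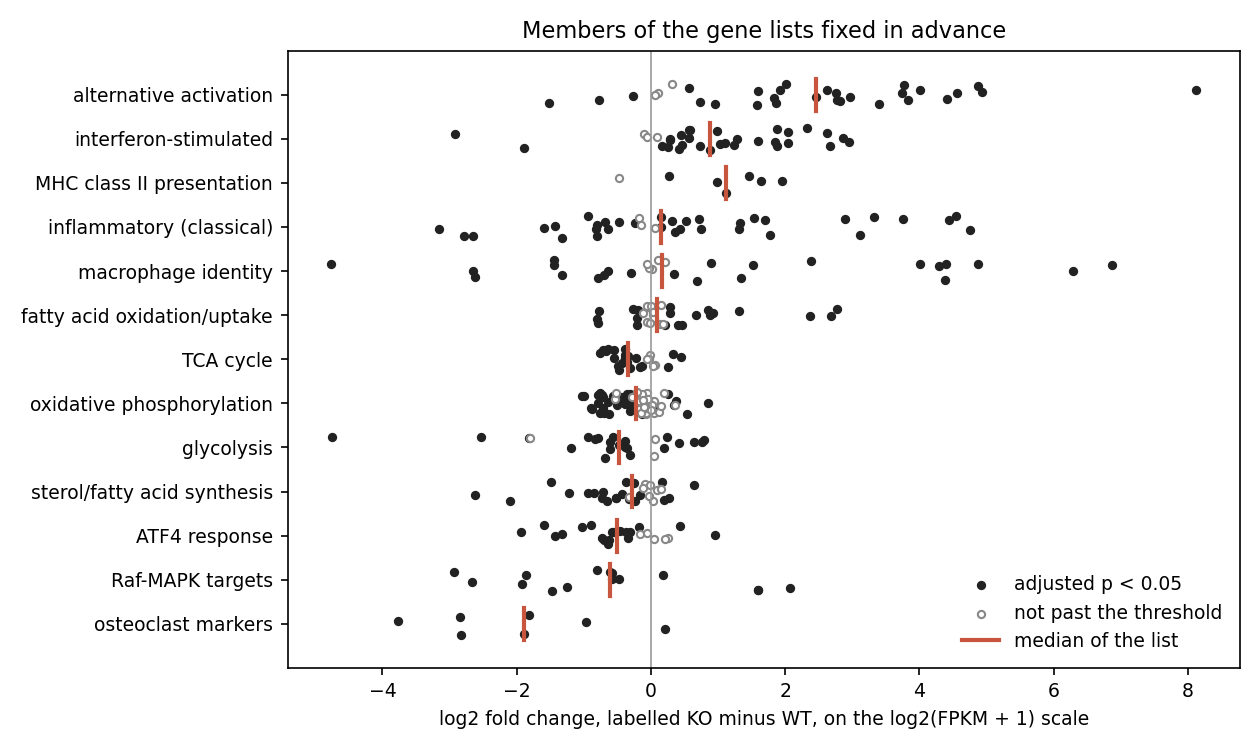
Log2 fold change on the log2(FPKM + 1) scale, KO-labelled minus WT (x axis), of the tested members of 13 gene lists, with filled points past an adjusted p of 0.05, open points not past it and a red bar at each list's median. The median of the alternative activation list is 2.46, that of glycolysis -0.47 and that of oxidative phosphorylation -0.22.

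Outside the central lists, interferon-stimulated genes were higher in KO-labelled cells. Of 33 tested, 28 rose, 2 fell and 3 did not pass, with a median log2 fold change of 0.88, or 0.57 over 41 without a filter and 0.58 over 21 with a mean of at least 5 FPKM. The chemokine gene Cxcl10 rose from 0.541 ± 0.209 to 10.8 ± 0.962 FPKM, while Ifi44l fell from 6.61 ± 1.07 FPKM to 0, at least 64.5-fold lower. Camera gave an adjusted p of 1.53e-06, and of 0.0462 with an estimated correlation. Of 7 tested genes of MHC class II presentation 6 rose and 1 did not pass, or 6 rose and 1 fell adjusted over the list alone, with H2-Ab1 at 0.0846 ± 0.0858 and 2.43 ± 0.677 FPKM (camera adjusted p = 0.0269, adjusted p = 0.216 with an estimated correlation). With an estimated correlation, only the alternative activation and interferon lists kept an adjusted p below 0.05 among the 25 lists tested.

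Several other metabolic and stress lists had more genes lower than higher, but lost their calls in the camera alternative with an estimated correlation. That estimate was -0.0133 for sterol synthesis, -0.0196 for ATF4 targets and -0.0979 for osteoclast markers, each below the preset 0.01. Correlation between genes therefore does not account for the lost calls of these lists. Sterol and fatty acid synthesis had 17 genes lower, 4 higher and 9 not passing of 30, led by the desaturase gene Scd1, which fell from 41.3 ± 0.755 to 5.91 ± 0.519 FPKM (camera adjusted p = 0.00635, adjusted p = 0.125 with an estimated correlation). Targets of the amino acid stress factor ATF4 had 17 of 24 lower, 2 higher and 5 not passing, or 17 and 3 adjusted over the list alone, and Chac1 fell from 10.4 ± 0.556 to 2.83 ± 0.797 FPKM (camera adjusted p = 0.00283, adjusted p = 0.125 with an estimated correlation). Osteoclast markers, included because macrophage precursors can take that fate, had 6 of 7 lower and 1 higher, with Acp5 falling from 50.8 ± 0.745 to 2.79 ± 0.260 FPKM (camera adjusted p = 0.00222, adjusted p = 0.125 with an estimated correlation). Arginine and polyamine genes had 12 of 18 higher, 2 lower and 4 not passing, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00635, adjusted p = 0.240 with an estimated correlation), and Arg1 and Slc7a2 are shared with the alternative activation list.

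Feedback targets of the Raf-MAPK pathway, the pathway of the v-raf oncogene used for immortalisation, had 11 of 15 lower and 4 higher, with Myc falling from 12.3 ± 1.83 to 1.10 ± 0.390 FPKM (camera adjusted p = 0.0269, adjusted p = 0.240 with an estimated correlation). Its adjusted p was 0.0672 when only genes with a mean of at least 5 FPKM were tested, 0.0670 without near-identical copies and 0.0705 with voom, with medians of -0.93, -0.60 and -0.83 over 10, 14 and 14 members against -0.61 over the 15. The list of Myc targets and ribosome biogenesis did not stand apart, with 5 higher, 12 lower and 15 not passing of 32 (camera adjusted p = 0.347), nor did the cell cycle list, with 8 higher, 15 lower and 15 not passing of 38 (camera adjusted p = 0.177).

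Macrophage identity genes moved in both directions, with 13 of 28 higher, 10 lower and 5 not passing (camera adjusted p = 0.254). Among TNF superfamily genes 10 of 17 rose, 6 fell and 1 did not pass (camera adjusted p = 0.208), and the TNF receptor gene Tnfrsf1b rose from 4.71 ± 0.0521 to 52.7 ± 4.55 FPKM. Lysosome genes had 17 of 32 higher, 6 lower and 9 not passing (camera adjusted p = 0.135, and 0.0299 under quantile normalization), and matrix and repair genes 7 of 21 higher, 12 lower and 2 not passing (camera adjusted p = 0.208), with Igf1 rising from 2.13 ± 0.240 to 94.2 ± 4.12 FPKM and a median and a mean log2 fold change of opposite sign (-0.45 and 0.0044). Cholesterol efflux genes had 5 of 9 higher, 1 lower and 3 not passing, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.111, and 0.0304 without a filter). The pentose phosphate list had 3 of 10 higher, 5 lower and 2 not passing (camera adjusted p = 0.386), and the hypoxia list 10 of 21 higher, 9 lower and 2 not passing, with Egln3 rising from 0.0921 ± 0.0643 to 44.6 ± 2.36 FPKM (camera adjusted p = 0.760, upward, with a median of -0.05).

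Markers of other cell types were mostly below the level for testing. Of 14 dendritic cell markers 2 were tested and both rose, Btla from 0 to 3.75 ± 0.139 FPKM (at least 91.0-fold) and Bst2, which is also in the interferon list, from 119 ± 1.92 to 134 ± 1.35 FPKM. The neutrophil list had 1 of 15 genes tested, Csf3r, which rose from 2.82 ± 0.699 to 43.9 ± 0.542 FPKM, and the erythroid and megakaryocyte list had 1 of 13, Pf4, which was at 0 in WT and at 16.3 ± 1.02 FPKM (at least 83.9-fold higher). Of 16 lymphocyte markers 2 were tested, of which Il7r rose from 0.194 ± 0.0850 to 1.84 ± 0.413 FPKM and Lck fell from 1.79 ± 0.194 to 0.771 ± 0.176 FPKM. The 1 tested fibroblast gene of 15, Acta2, rose from 0.306 ± 0.0865 to 2.17 ± 0.546 FPKM, and none of 12 mast cell and basophil markers was tested.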

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

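The fit without genes that have a near-identical copy and the voom fit were chosen after the data had been seen. Tnfsf9 stayed below the threshold under all alternatives, with adjusted p from 0.0548 (without WT replicate 2, log2 fold change -0.26) to 0.737 (without WT replicate 1, -0.03). The genes past an adjusted p of 0.05 numbered 5835 to 6446 when 1 library was left out, and those past 2-fold as well 1455 to 1485. With only genes of at least 5 FPKM tested (7290), 786 genes passed 2-fold, all among the 1465, since fewer genes entered. Rescaling to TPM shifted the median of all genes to 0.10 and put 60.0% of 6611 changed genes higher, against 50.4% as deposited. With voom 6844 and 1822 genes passed. Among the 6 central lists, the call was lost with an estimated correlation for glycolysis (adjusted p = 0.283), oxidative phosphorylation (0.125) and the TCA cycle (0.173), and without near-identical copies for glycolysis (0.0743), where the median over 18 of 25 members was -0.38 against -0.47. Of the named genes, Ldha alone changed sign, to 0.0038 under quantile normalization (adjusted p = 0.932), and the cause was not tested. The replicate numbers do not pair the libraries, since same-numbered libraries deviated with r of -0.03, 0.05 and -0.03, and with the replicate number as a block 6194 and 1472 genes passed. Depth limits statements on genes of a few fragments, such as Retnla with 12.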

Other observations

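The Y-linked test, the read-assignment test and the splice-junction test were chosen after the results were seen, and the gene families and the genes that the naming rule does not take were chosen after their values were seen, except the 3 strain markers H2-Ea-ps, Ifi202b and Gbp2b.

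Of 18 gene families counted, some moved in 1 direction and others in both. All 6 tested genes of Fc receptors, the receptors of antibodies, and of their gamma chain rose, from Fcgr3 (0.409 ± 0.344 to 76.7 ± 3.14 FPKM) and Fcgr2b (0.564 ± 0.203 to 44.7 ± 5.27 FPKM) to Fcer1g (149 ± 4.88 to 189 ± 6.66 FPKM). Of 7 complement genes 6 rose, among them C3 (9.74 ± 0.249 to 215 ± 2.56 FPKM) and C1qc (0 to 28.3 ± 1.17 FPKM, at least 390-fold higher), and the properdin gene Cfp fell from 84.1 ± 0.649 to 28.2 ± 4.57 FPKM. Adgre1, which encodes the macrophage marker F4/80, rose from 11.8 ± 0.625 to 268 ± 6.07 FPKM, while the fractalkine receptor gene Cx3cr1 fell from 26.3 ± 1.63 FPKM to 0 (at least 840-fold lower), and Spi1, the myeloid transcription factor, was at 135 ± 1.79 and 137 ± 7.61 FPKM with a limma adjusted p of 0.763 (Benjamini-Hochberg). C3 and Adgre1 start on chromosome 17 at 57203970 and 57358691, close to Tnfsf9 at 57105325. Whether their change comes from altered DNA near the targeted gene was not tested. The ATP receptor gene P2rx7 rose from 2.67 ± 0.340 to 151 ± 2.87 FPKM. All 4 tested Ms4a genes rose, as did the 4 tested Ifi200 genes and the 4 tested Gbp genes, while Ifi202b and Gbp2b, below the level for testing, were at 0.958 and 0.165 FPKM in WT and at 0 in KO-labelled libraries, and both tested Rhox genes fell. Other families were mixed, with 6 higher and 4 lower of 11 Clec genes, 8 and 7 of 26 Trim genes, 2 and 3 of 6 Adam genes, 3 and 2 of 8 tetraspanin genes, 12 and 4 of 16 genes of interleukin receptors and their accessory chains and 1 and 2 of 4 chemokine receptor genes. Csf1r, the receptor gene of a macrophage growth factor, fell from 232 ± 1.22 to 134 ± 2.95 FPKM, so these genes do not add up to a single direction for macrophage genes.

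The groups differed in 6594 genes. Differences between chromosomes held 1.12% of the variance of log2 fold changes over 10795 genes, so whole chromosomes gained or lost explain little of that variance. Large changes of single genes weigh most in it, so it says little on smaller shifts of a chromosome, which stay open. The median log2 fold changes of chromosomes 1 to 19 and X ran from -0.28 (chromosome 12) to 0.18 (chromosome 16). Within 5 Mb of Tnfsf9, 4 of 51 tested genes passed 2-fold, which is 0.273% of all that did. So few tested genes could never make up a large share, so this share does not decide whether DNA flanking the targeted gene differs, which stays open. In that window 7.84% of tested genes passed 2-fold, against 13.5% elsewhere (Fisher's exact test p = 0.305), and C3 and Adgre1 are among the 4. All 4 Y-linked genes examined had fragments in every KO-labelled library and fewer than 3 over the WT libraries, and Xist had 0 in all 6, which is consistent with each group being a line with its own history and leaves the origin of the Y-linked difference open. That history and the genotype cannot be told apart, because the labels do not say how many lines stand behind each group and all KO-labelled libraries part from all WT libraries, and an effect of 4-1BBL stays open and untested.

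Mycn had the largest decrease among the genes the naming rule took, from 280 ± 4.53 to 0.0301 ± 0.0289 FPKM, between lines immortalised with v-myc. Extra copies of its chromosome region in the WT line were tested as an explanation. The 7 other tested genes within 1 Mb had a median log2 fold change of -0.34 and went both ways, from -1.70 for Gm6736 over -0.35 for Ddx1 to 2.17 for Fam49a, against -8.09 for Mycn and a median of -0.28 for chromosome 12. This argues against extra copies of the whole region as the source, while a gain of Mycn alone stays open, and whether Mycn was gained in the WT line or lost in the KO-labelled one was not tested.

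Some ribosomal protein genes and their near-identical copies moved apart, in 13 of 66 families by 2-fold or more. In 3 of the 13 the summed fragments also differed by 2-fold or more (log2 1.96 for Rpl35a, 1.61 for Rps18 and 1.54 for Rpl29), against 0 of the other 53. Fragments of 1 transcript assigned to different copies would keep the sums only if fragments that map to several places were counted. Their treatment is not given, so the sums do not decide, and such assignment stays open for all 13. The copies were favoured in WT in 11 of the 13 and in KO-labelled libraries in 2, so a loss of fragments over splice junctions in WT stays open for the 11 and would move the 2 the other way. Mice of different strains behind the lines stay open, since 0 of 3 genes that differ between strains reached 5 FPKM in 1 group and stayed under 0.1 in the other, the limits of the test. H2-Ea-ps was at 0 in all 6 libraries, Gbp2b at 0.165 ± 0.257 FPKM in WT and 0 in KO-labelled libraries, and Ifi202b was present in WT alone (0.958 ± 0.321 FPKM, 104 fragments). Nnt, which C57BL/6J mice lack in part, had 21 fragments over the WT and 32 over the KO-labelled libraries. Its low count is uncertain, since 47.45% of its exon length overlaps a second Nnt entry on the same strand, which was at 0 FPKM.

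Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. All splits but the real one mix WT and KO-labelled libraries on both sides. The group difference then adds to the spread within each side, which holds down their gene counts, and part of it remains in their list p-values. These splits are therefore not free of the group difference, and no conclusion is drawn from them. The real split gave 6594 and 1465 genes and the highest of the others 0 and 0, so 1 split of 10 reached each count. For the lists, the camera p of the real split and the smallest of the others were 2.75e-11 and 2.10e-05 for alternative activation, 0.00275 and 0.00714 for glycolysis, 2.64e-05 and 2.73e-05 for oxidative phosphorylation, 0.00163 and 0.00216 for the TCA cycle and 0.0921 and 0.145 for fatty acid oxidation, each with 1 split as small. For the inflammatory list they were 0.253 and 0.150, with 2 splits as small.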
